A study of Homo sapiens with 11 samples.

How the data were processed

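The series holds 11 RNA libraries of CD141-positive dendritic cells, 5 from peripheral blood of healthy subjects and 6 from synovial fluid of subjects with inflammatory arthritis. Mononuclear cells were taken over a density gradient and CD141-positive cells were pulled out with antibody-coupled magnetic beads, per the labels' protocols. Libraries were made with the NuGen Ovation Universal RNA-Seq kit and sequenced as paired ends on a NextSeq500, pooled in a batch of 6 and a batch of 5, per the labels. Which library was in which pool is not given. It was inferred from the index numbers in the sample descriptions, which place 2 blood and 3 synovial fluid libraries in one pool and 3 and 3 in the other. By its expression 1 library did not match the cell type of its group's labels. Whether its sort, its label or the state of its cells is the cause was not settled. It was kept under its label, so every group mean and count includes it unless stated.

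The authors deposited a table of expected counts for 31200 features, with a column per library, not scaled between libraries. The aligner, the counter, the genome build and the annotation are not given in the sources used here. Feature names hold a gene symbol, a chromosome, a strand and a running number, and symbols of 23467 features matched a current or older symbol of the reference tables, which were used for names only. No coordinates are given because the build is not known. Of the counts 7.27% of values were not whole (tolerance 0.001), as when reads are shared among overlapping or similar genes, and whether counting used strand is not stated. Antisense and overlapping genes therefore cannot be told apart. The estimated counts as deposited were rounded to whole numbers before any test. The table has 0 mitochondrially encoded features, so the planned comparison of the mitochondrial share was not run.

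Genes were kept with edgeR's filterByExpr by group, which left 13758, and libraries were scaled by TMM. Each gene was tested for synovial fluid against blood with edgeR (4.0.16) glmQLFit and glmQLFTest, with the group as the only term, two-sided, and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes and are given as mean ± SD over the libraries of a group. Gene lists, fixed before the data were examined, were tested with camera in limma (3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 31 of 36 lists with at least 5 tested members. Camera with an estimated correlation and fry were run as alternatives. Lists for neutrophils, platelets, erythroid cells, endothelial cells, and mast cells and basophils had 2, 4, 0, 3 and 2 tested members and were not tested. The number of genes detected and 4 further library measures were compared by two-sided exact permutation tests over all 462 assignments.

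Named genes were chosen by a rule set before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups. It adds up to 4 members of each list with the smallest adjusted p, and a fixed set of dendritic cell, cytokine and co-stimulation genes. The text names a part of these. XIST, Y-linked genes, polymorphic HLA genes, other genes whose expression follows germline genotype, receptor segments and rows without a usable symbol are never named. These classes stayed in the fits.

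Alternatives were DESeq2 size factors or library totals in place of TMM, no filter, a filter of CPM above 1 in at least 5 libraries, DESeq2 (1.42.0), limma voom with quality weights, a fold change of at least 2, the inferred pool as a term, each pool alone, the label number as a block, and each library left out in turn. A pair of settings that leave out libraries standing apart was added after the data were seen. All ran in R 4.3.3.

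The tests were run first on simulated counts for the 13758 genes, drawn from the real means, library sizes and dispersions, with 200 genes changed. Of 50 genes changed by 1, 2, 3 and 4 log2 units, edgeR called 1, 12, 25 and 29, all with the right sign, and 4 unchanged genes were called beside them. With no gene changed 0 were called. Most changes of 2 log2 units or less were thus missed in this simulation. It changed fewer genes than were called in the data and drew the noise of each gene independently. Its rates are therefore only a rough guide to what these libraries can detect. Total counts of 11530640 to 22645159 allow a transcript with 0 counts in blood library 1 a level of up to 0.238 CPM (3 counts). Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.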

Results

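RNA of CD141-positive dendritic cells was sequenced from peripheral blood of healthy subjects (5 libraries, labelled 1, 2, 4, 5 and 6) and from synovial fluid, the fluid of the joint cavity, of subjects with inflammatory arthritis (6 libraries, labelled 1 to 6). Each subject gave a single RNA sample, so the libraries of a group are separate subjects. Their spread holds differences between people together with those of sorting, library preparation and sequencing, which cannot be separated. CD141, the product of THBD, is a surface protein that marks type 1 conventional dendritic cells in human blood, a cell type specialised in presenting antigen to CD8 T cells, and it is also found on other myeloid cells. Total counts ran from 11530640 to 22645159 per library, with a mean of 13108500 in blood and 17078400 in synovial fluid. The comparison asks how the cells of the inflamed joint differ in expression from the cells of healthy blood. Tissue and disease change together in it, so neither can be separated from the other.

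Synovial fluid cells carried far more FN1, CCND1, GNAO1 and XCR1 transcript than blood cells, and far less PDE4D, HBEGF, CEBPB and FOS. Of 13758 genes tested with edgeR's quasi-likelihood test, 424 were higher and 374 were lower in synovial fluid at a Benjamini-Hochberg adjusted p under 0.05. At least a 2-fold change was fitted for 408 of the higher and 336 of the lower genes. In 548 of the called genes the blood and synovial fluid libraries did not overlap. Of all tested genes 959 did not overlap, where chance gives 0.433%. The spread between libraries of a group was wide, with a biological coefficient of variation of 83.3%. Blood library 1 stood apart from the other blood libraries, with a median correlation of 0.650 with its own group, where the nearest of the others had 0.816. Without it 1380 of 14105 tested genes were higher and 1180 lower, and 793 of the original calls were shared. Counts of list members called without this library, given below, stand against that larger share of calls. Leaving out blood library 4 gave 133 higher and 104 lower genes, and leaving out blood library 5 gave 133 and 96. Within the inferred sequencing pool of 5 libraries (2 blood, 3 synovial fluid) edgeR called 0 genes, with 1131 at an unadjusted p under 0.05, and within the pool of 6 libraries it called 190 higher and 193 lower. Blood library 1 was 1 of the 2 blood libraries in the pool of 5. With the pool as a term in the fit the counts were 303 and 232.

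**Figure D1:**
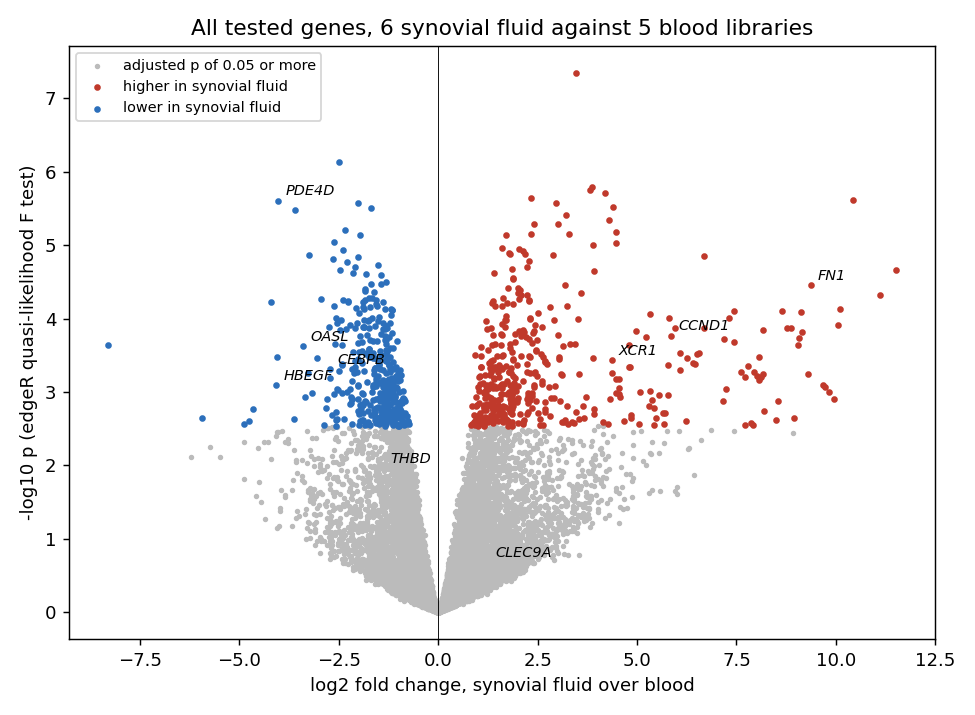
Each point is 1 of the tested genes, with the log2 fold change of synovial fluid over blood on the horizontal axis and -log10 of the edgeR p on the vertical axis. Red points are genes higher and blue points genes lower in synovial fluid at an adjusted p under 0.05, with FN1 at 9.37 and PDE4D at -4.02, and some of the genes excluded from naming are not drawn.

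Among the genes with the largest rises, FN1 (chromosome 2), which encodes the matrix glycoprotein fibronectin, went from 1.96 ± 2.11 CPM in blood (SD, n = 5) to 1309 ± 1792 CPM in synovial fluid (SD, n = 6), a log2 fold change of 9.37 ± 1.51 (SE, edgeR adjusted p = 0.00834). Synovial fluid library 4 held 4861 CPM, and without it the log2 fold change of FN1 was 8.21 and still called. CCND1 (chromosome 11), the G1 cyclin D1, rose from 9.87 ± 6.38 to 571 ± 535 CPM, by 5.85 ± 1.12 on the log2 scale (edgeR adjusted p = 0.0132), and by 5.19 without synovial fluid library 3. GNAO1 (chromosome 16), a G protein alpha subunit, rose from 6.24 ± 3.95 to 253 ± 152 CPM, by 5.34 ± 0.95 (edgeR adjusted p = 0.0108). LIMCH1, CST7, a cysteine protease inhibitor of immune cells, and ADAM19, a membrane metalloprotease, rose by 5.80, 5.22 and 4.97 on the log2 scale. S100B, PPAP2A, IL21R, the receptor of interleukin 21, and TBC1D4 rose by 4.83, 4.80, 4.56 and 4.56. PPAP2A had fractional counts in 10 libraries, so part of its reads was shared with other features. Without synovial fluid library 5 the log2 fold changes of LIMCH1, CST7, ADAM19, IL21R and TBC1D4 were smaller, at 4.31, 3.65, 3.51, 3.49 and 2.76, and still called. The call of TBC1D4 was lost without any of 4 single blood libraries (2, 4, 5 or 6), and that of IL21R without any of 6 single libraries (blood 4, 5 or 6, synovial fluid 1, 3 or 6). That of S100B was lost without blood library 4 and without blood library 5, and that of PPAP2A without blood library 4.

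Among the genes with the largest falls, PDE4D (chromosome 5), a cyclic AMP phosphodiesterase, went from 156 ± 61.0 to 9.63 ± 5.66 CPM, a log2 fold change of -4.02 ± 0.50 (edgeR adjusted p = 0.00351). HBEGF, an EGF receptor ligand, went from 146 ± 142 to 8.69 ± 7.72 CPM (-4.07 ± 0.93, edgeR adjusted p = 0.0272), and its call was lost with the pool term and without any of 5 single libraries, with -3.46 without blood library 4. CCDC88C, OASL, SHB and SMOX fell by 3.59, 3.40, 3.24 and 3.05 on the log2 scale, and DNMBP and AHDC1 fell by 2.75 and 2.63. OASL stood at 112 CPM in blood library 1, and without it the log2 fold change was -2.45 and still called. CEBPB (chromosome 20), a transcription factor of myeloid and inflammatory gene expression, fell from 205 ± 123 to 31.3 ± 22.6 CPM (-2.71 ± 0.58, edgeR adjusted p = 0.0212), a call lost without blood library 4 and without blood library 5. The SMOX call was lost without blood library 4. FOS (chromosome 14), an immediate early transcription factor, fell from 2544 ± 438 to 411 ± 204 CPM (-2.63 ± 0.37, edgeR adjusted p = 0.00508).

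**Figure D2:**
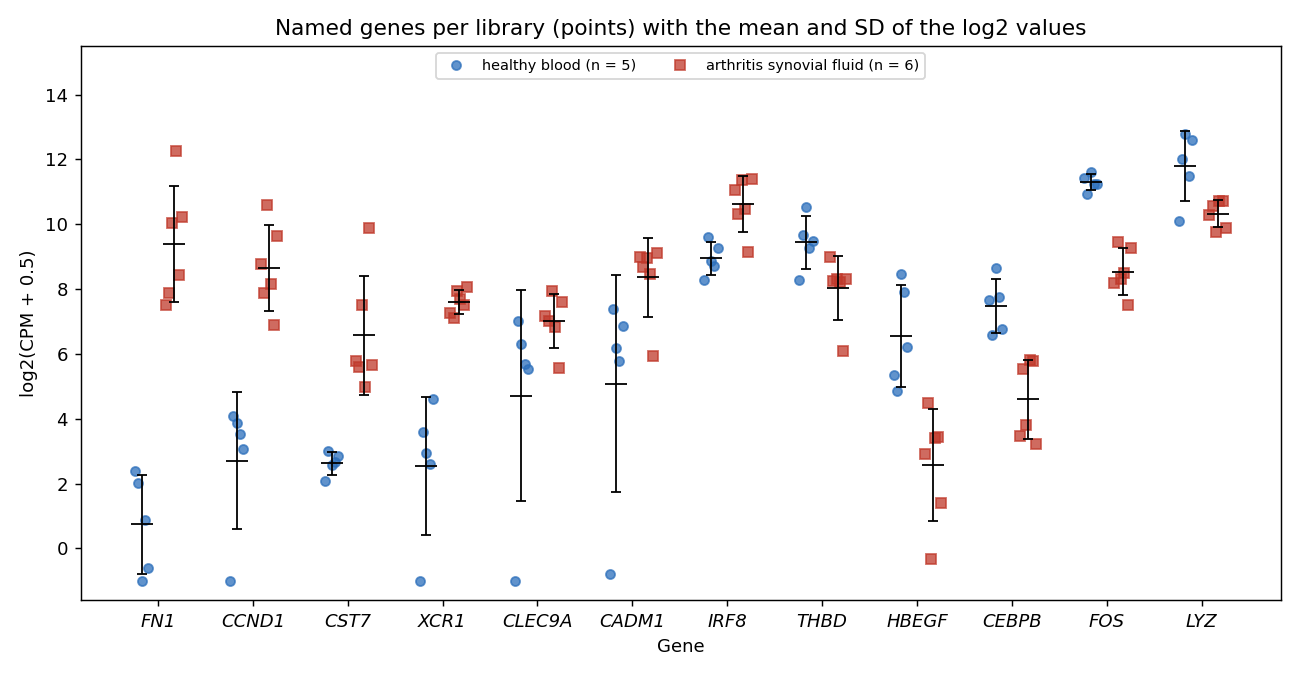
Points are single libraries (blue circles, 5 healthy blood; red squares, 6 synovial fluid) on a scale of log2(CPM + 0.5), and black bars give the mean and SD of the log2 values. FN1, CCND1, CST7 and XCR1 have every synovial fluid library above every blood library, HBEGF, CEBPB and FOS every one below, and CLEC9A, CADM1, IRF8, THBD and LYZ overlap.

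Some genes that mark type 1 conventional dendritic cells rose in synovial fluid. Of the 19 tested members of this list 4 rose and 0 fell, and 5 rose when adjusted over the list alone. XCR1 (chromosome 3), the receptor of the chemokine XCL1, rose from 9.69 ± 9.01 to 199 ± 51.8 CPM (4.36 ± 0.91, edgeR adjusted p = 0.0188). SNX22, SLAMF8 and IRF8, the last a transcription factor needed for this cell type, rose by 3.04, 3.15 and 1.79 on the log2 scale. SNX22 had fractional counts in 11 libraries and SLAMF8 in 9. CLEC9A had a log2 fold change of 1.25 ± 0.94 (edgeR adjusted p = 0.482), CADM1 2.28 ± 0.98 (adjusted p = 0.192) and BATF3 1.16 ± 0.89 (adjusted p = 0.491). The median of the list was 1.65, with an adjusted p of 0.00114 by camera, and the adjusted p = 0.821 with an estimated correlation. Blood library 1 had 0 counts of CLEC9A, XCR1 and BATF3, which allows up to 0.238 CPM each. SLAMF8 did not follow them, at 27.5 CPM in that library and 4.22 to 29.9 CPM in the other blood libraries. Without blood library 1, 10 members rose, CADM1 among them (adjusted p = 0.0306), and the median was 1.44. In that fit 2560 of all 14105 tested genes were called. CLEC9A and BATF3 had smaller log2 fold changes there, 0.88 and 0.78 (edgeR adjusted p = 0.189 and 0.256). TLR3 had -1.89 (adjusted p = 0.0508), also not called. The calls of XCR1 and SNX22 were lost without blood library 4 and without blood library 5. That of SLAMF8 was lost without blood library 4, and that of IRF8 without any of 6 single libraries. THBD, the gene of the sort antigen itself, stood at 784 ± 427 CPM in blood and 302 ± 140 CPM in synovial fluid (-1.38 ± 0.46, edgeR adjusted p = 0.101), and without blood library 1 it fell (-1.64, adjusted p = 0.0227).

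Of the antigen presentation genes 2 of class II and 1 of class I passed the test, where 5.80% of all tested genes did. In the MHC class II list 2 of 14 members rose and 0 fell: CIITA, the master regulator of class II transcription, by 2.26 ± 0.54 (edgeR adjusted p = 0.0320), and RFX5, a class II promoter factor, by 1.58 ± 0.30 (adjusted p = 0.0131). Adjusted over the list alone 2 rose and 1 fell, and camera gave an adjusted p of 0.0727. In blood library 1 the mean log2 CPM of this list was 6.49, the lowest of the blood libraries. Without that library the class II list had 3 up and 0 down (camera adjusted p = 0.316), and the class I list 3 up and 1 down. The fit without it called 2560 of all 14105 tested genes, a larger share than 5.80%. In the MHC class I list 1 of 18 rose, TAP2, a subunit of the peptide transporter, by 1.202 ± 0.28 (adjusted p = 0.0294). TAP2 had fractional counts in 10 libraries and CIITA in 1. The call of CIITA was lost without any of 5 single libraries (blood 4, 5 or 6, synovial fluid 3 or 6) and that of TAP2 without any of 6 (blood 2, 4 or 5, synovial fluid 1, 3 or 6), while RFX5 was called with any single library left out.

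Genes of dendritic cell maturation and of cytokine production did not pass the test as groups. None of the 19 tested maturation genes was called (camera adjusted p = 0.174, median log2 fold change 2.20). CD40 stood at 22.2 ± 5.15 CPM in blood and 130 ± 163 CPM in synovial fluid (2.55 ± 0.69, edgeR adjusted p = 0.05003, just over the threshold), CD80 at 4.43 ± 7.39 and 130 ± 290 CPM (adjusted p = 0.124), CCR7, the homing receptor of mature dendritic cells, at 12.6 ± 21.0 and 600 ± 1405 CPM (adjusted p = 0.145). CD83 and CD86 had adjusted p of 0.822 and 0.290. Without synovial fluid library 5 the log2 fold changes of CD40, CD80 and CCR7 were 1.58, 1.54 and 1.16, with CD40 called (edgeR adjusted p = 0.0383), and those of CD86 and CD83 went from 0.97 to 0.26 and from 0.38 to -0.52. Without blood library 1, 6 maturation genes rose, CD80 and CD40 among them. The log2 fold changes of CD80 and CCR7 were then 6.77 and 7.45, with CCR7 not called (edgeR adjusted p = 0.0538). CCR7 stood at 49.9 CPM in blood library 1 and at 0 to 6.73 CPM in the other blood libraries. Synovial fluid library 5 had a mean log2 CPM of 9.83 over this list, where the next highest synovial fluid library had 5.58. Of the 23 tested cytokines and chemokines 0 were called: TNF had a log2 fold change of 0.46 ± 0.88, IL6 -1.58 ± 1.85, IL1B -0.45 ± 1.66 and IL8 -1.40 ± 1.21, with edgeR adjusted p of 0.813, 0.672, 0.908 and 0.551. The sign of TNF turned without synovial fluid library 2 (-0.96) and that of IL1B without blood library 1 (1.97), while IL1B had -1.66 without synovial fluid library 2. IL8 had -0.69 without blood library 1 and -2.62 without synovial fluid library 5. Among the 21 tested NF-kB targets 0 were called, and camera placed the list lower (adjusted p = 0.0169, and adjusted p = 0.916 with an estimated correlation), with a median of -0.23 and a mean of 0.08. That call was lost without blood library 1 (adjusted p = 0.139, median 0.55), and also without synovial fluid library 3, 4 or 6.

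The mean log2 CPM of the interferon-stimulated gene list was 8.24 in blood library 1, where the next highest library of either group, blood library 4, had 4.66. Of the 23 tested members 1 fell, OASL, and 11 fell when adjusted over the list alone, with a median log2 fold change of -2.22 (camera adjusted p = 0.0566). IFI44L stood at 1095 CPM in blood library 1 and at 3.16 to 101 CPM in the other blood libraries, against 8.28 ± 5.89 CPM in synovial fluid. Without that library the log2 fold change of IFI44L went from -4.88 to -1.92, and the median of the list was 0.17, with 3 members up and 1 down. In the interferon gamma response list 1 of 18 members rose, CIITA (camera adjusted p = 0.501), and CXCL9 stood at 4.91 ± 2.36 and 184 ± 384 CPM (adjusted p = 0.0937). Synovial fluid library 5 held 964 CPM of CXCL9, and the log2 fold change was 5.22 with it and 2.49 without it.

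Stress and metabolism lists held few single calls. Among 22 immediate early and heat shock genes 2 fell, FOS and JUN (-1.91 ± 0.50, edgeR adjusted p = 0.0463), and 3 fell when adjusted over the list alone. Camera placed this list lower (adjusted p = 0.00353, and adjusted p = 0.821 with an estimated correlation), with a median log2 fold change of only -0.17. The median ran from -0.57 to -0.012 as each library was left out. FOS was called with any single library left out, and JUN was lost without any of 8. JUN was at 2012 CPM in blood library 1, and without it the log2 fold change was -1.13 and still called. Of 19 unfolded protein response genes 1 rose, MANF (1.84 ± 0.40), and 1 fell, DNAJC3 (-1.32 ± 0.27), with a camera adjusted p of 0.879. Of 25 oxidative phosphorylation genes 1 rose, SDHC (1.504 ± 0.37), with a camera adjusted p of 0.452. Without blood library 1 camera called this list lower (adjusted p = 0.0248, median -0.54), with 1 member up and 3 down. The MANF call was lost without any of 4 single libraries and that of SDHC without any of 7. Glycolysis (22 tested) and hypoxia response (20 tested) had 0 calls over all genes, with medians of -0.21 and -0.92 and camera adjusted p of 0.501 and 0.174. Their means in blood library 1 were the highest of the blood libraries, at 8.77 and 7.21 log2 CPM. Without it the medians were 0.55 and 0.52. HK2 stood at 466 ± 937 CPM in blood and 120 ± 201 CPM in synovial fluid (-1.96, adjusted p = 0.403), with 2141 CPM in blood library 1 and a log2 fold change of 1.30 without it (adjusted p = 0.371), and VEGFA at 385 ± 435 and 148 ± 260 CPM (-1.38, adjusted p = 0.503). Without blood library 1 VEGFA had a log2 fold change of -0.46. Without synovial fluid library 5 HK2 and VEGFA had -3.52 and -3.03, not called. Among the 19 tested cell cycle genes 0 were called singly, while the median was 1.38 (camera adjusted p = 0.00142, and adjusted p = 0.821 with an estimated correlation). MCM5, a replication helicase subunit, had a log2 fold change of 1.43 ± 0.43 (edgeR adjusted p = 0.0712), and PCNA 1.23 ± 0.46 (adjusted p = 0.136). Of 26 ribosomal protein genes 0 were called (median -0.47, camera adjusted p = 0.0216, and adjusted p = 0.916 with an estimated correlation). The list call was lost without any of 5 single libraries (blood 2, 4 or 6, synovial fluid 4 or 5). Blood library 1 had the lowest mean of the blood libraries for this list, 6.93 log2 CPM, and without it 22 of the 26 fell, RPL37 among them (-1.20, adjusted p = 0.00386).

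Innate receptor and surface molecule lists held few single calls, and none of these lists passed camera. Of 22 toll-like receptor pathway genes 1 rose, TLR10 (2.91 ± 0.70, edgeR adjusted p = 0.0332), and 1 fell, the receptor-associated kinase IRAK1 (-1.28 ± 0.29, adjusted p = 0.0263). In the TREM and DAP12 list 1 of 14 rose, PLCG2 (0.89 ± 0.23, adjusted p = 0.0426), and 1 fell, TREM1, an amplifier of myeloid inflammatory responses (-2.86 ± 0.78, adjusted p = 0.0496). The TREM1 call was lost without any of 10 single libraries, among them blood library 1 (-2.00, adjusted p = 0.0551). Those of PLCG2 and TLR10 were each lost without any of 8, and that of IRAK1 without any of 4. With the inferred pool as a term TREM1, PLCG2 and TLR10 were no longer called. Of 15 co-inhibitory molecules 2 rose: HAVCR2, which encodes TIM-3, by 1.76 ± 0.29 (adjusted p = 0.00887), and CD200R1, which had 0.101 ± 0.225 CPM in blood and 18.2 ± 14.1 CPM in synovial fluid. Of 18 chemokine receptor and homing genes 1 rose, SELPLG, the selectin ligand PSGL-1, from 21.0 ± 10.03 to 193 ± 75.4 CPM (3.20 ± 0.42, adjusted p = 0.00377). Of 18 scavenger receptor and lipid genes 2 rose, FABP5 (2.29 ± 0.39) and APOE (4.84 ± 1.25), and APOE was lost without any of 8 single libraries, with 3.67 without synovial fluid library 4. Complement (18 tested) and matrix remodelling (18 tested) had 0 calls. Camera adjusted p for these 6 lists were 0.758, 0.369, 0.817, 0.928, 0.211 and 0.758, and 0.638 for matrix remodelling. Without blood library 1, 4 of 20 tested matrix genes and 6 scavenger receptor and lipid genes rose, and 0 fell in either list. Complement then had 1 up and 1 down. Of all 14105 genes tested without that library 2560 were called. MMP14 stood at 1158 CPM in blood library 1 and at most at 2.80 CPM in the other blood libraries. Its log2 fold change was -3.33 with blood library 1 and 4.13 without it (edgeR adjusted p = 0.0454).

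Markers of other cell types were measured because the sort enriches cells by a single antigen. In the macrophage list 1 of 13 tested members rose, APOE, and camera gave an adjusted p of 0.0566 and a median of 1.89. CD163, a scavenger receptor, and VSIG4, a complement receptor, had log2 fold changes of 2.99 and 3.96, with edgeR adjusted p of 0.116 and 0.0787, and 1.76 and 2.35 without synovial fluid library 4. In the monocyte list 1 of 15 fell, LYZ, the gene of lysozyme, from 4248 ± 2403 to 1325 ± 362 CPM (-1.68 ± 0.44, adjusted p = 0.0428), and camera gave 0.0505. LYZ had fractional counts in 10 libraries, and its call was lost without any of 9 single libraries. CD14 stood at 85.6 ± 144 and 113 ± 159 CPM (0.41, adjusted p = 0.871), with 343 CPM in blood library 1 and a log2 fold change of 2.35 without it (adjusted p = 0.120) and of -0.75 without synovial fluid library 4. THBS1 stood at 6419 ± 11971 and 142 ± 255 CPM (-5.49, edgeR adjusted p = 0.0816), with 27761 CPM in blood library 1. Its log2 fold change was -2.98 without that library (edgeR adjusted p = 0.157) and -7.23 and called without synovial fluid library 5 (adjusted p = 0.0296). Of 14 listed B cell markers only 6 passed the filter on low counts. Of these 0 were called over all genes and 3 fell when adjusted over the list alone, with a median of -2.30 (camera adjusted p = 0.00388, and adjusted p = 0.370 with an estimated correlation). MS4A1 and PAX5 were low, at 10.5 ± 6.45 and 3.38 ± 2.05 CPM in blood and 0.816 ± 1.21 and 0.133 ± 0.234 CPM in synovial fluid. Of 16 listed synovial fibroblast markers only 5 passed the filter on low counts, so the list result covers those alone. Among the 5, FN1 and COL6A1 rose, with a median of 3.43 (camera adjusted p = 0.0178, and adjusted p = 0.726 with an estimated correlation). COL6A1 reached 26.0 ± 15.2 CPM in synovial fluid, and its call was lost with the pool term and without any of 8 single libraries. COL1A1, the main fibroblast collagen, stood at 3.45 ± 4.46 CPM in blood and 0.778 ± 0.468 CPM in synovial fluid. Blood library 4 held 10.6 CPM of it, and the log2 fold change was -2.15 with that library and -1.10 without it, not called in either fit. In the NK cell list 1 of 7 rose, NCAM1 (3.41 ± 0.92, adjusted p = 0.0487), a call lost without any of 9 single libraries. The calls of LYZ, JUN and NCAM1 were also lost with the pool term. Type 2 dendritic cell, plasmacytoid dendritic cell, T cell and plasma cell markers had 0 calls among 8, 12, 11 and 6 tested members, with CD1C at 7.92 ± 5.84 and 20.5 ± 19.2 CPM. Camera adjusted p for these 4 lists were 0.758, 0.452, 0.0727 and 0.872, and 0.211 for NK cell markers.

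**Figure D3:**
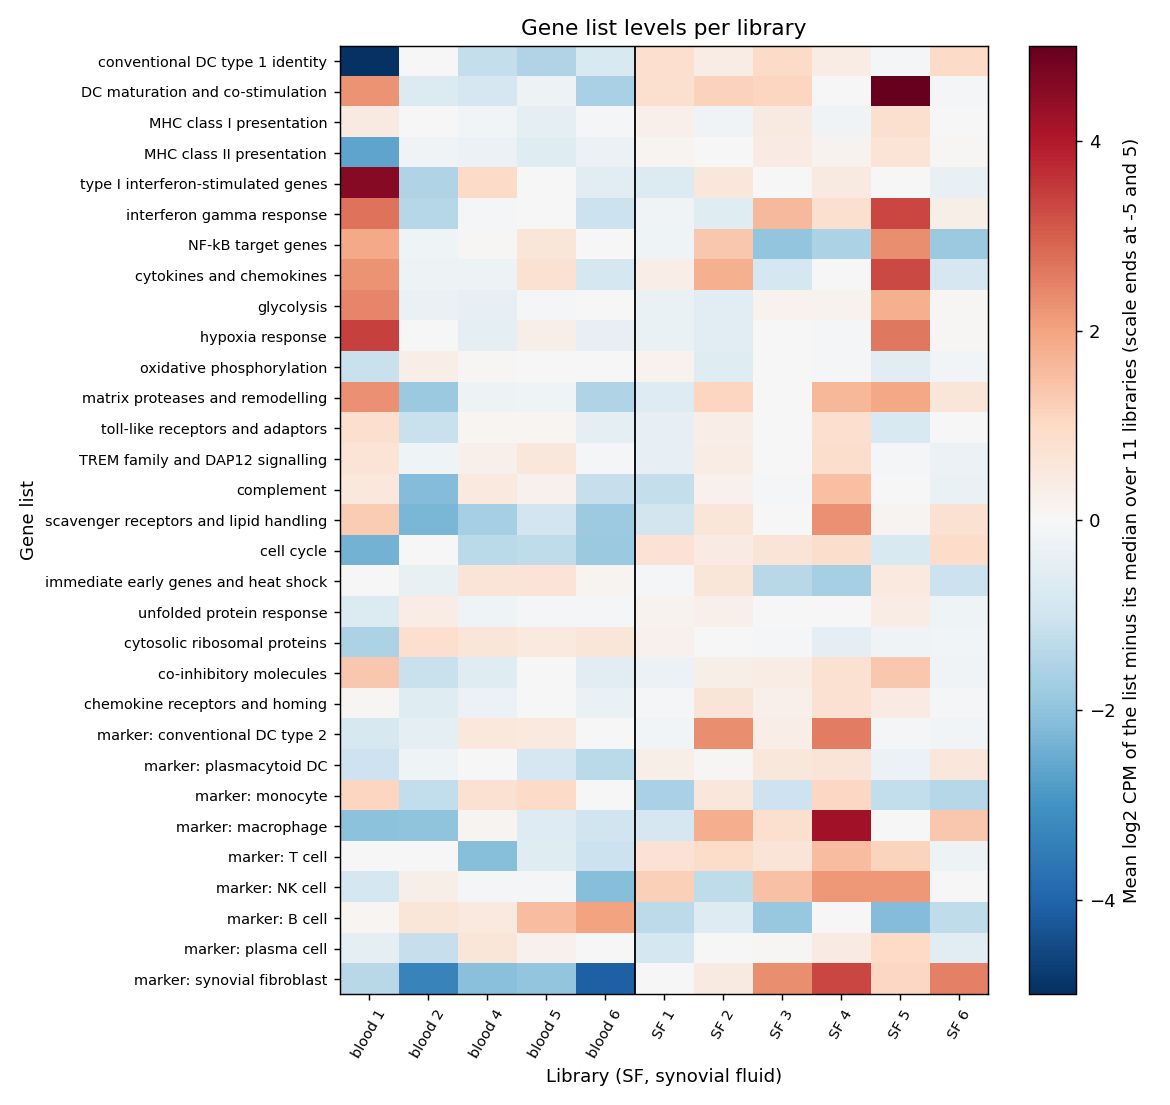
Rows are the 31 tested gene lists and columns the 11 libraries, with colour giving the mean log2 CPM of a list minus its median over the libraries. Blood library 1 is low for type 1 dendritic cell genes and high for interferon-stimulated genes, and synovial fluid library 5 is high for maturation genes (mean log2 CPM 9.83).

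Across the lists, camera with a preset correlation called 7 of 31, 3 higher and 4 lower. With the correlation estimated from the data it called 0, and 74 of 100 splits of the libraries into groups of 5 and 6, the real one included, called at least 7 lists. The fry test called 5 lists, of which cell cycle, B cell and synovial fibroblast markers were also called by camera. The others were plasmacytoid dendritic cell and T cell markers (both higher, fry adjusted p = 0.0409). The type 1 dendritic cell, NF-kB, immediate early and ribosomal protein lists had fry adjusted p of 0.0505, 0.535, 0.226 and 0.658. In 7 lists the median, the mean and the camera direction differed in sign: NF-kB targets, cytokines and chemokines, toll-like receptors, complement, co-inhibitory molecules, monocyte markers and plasma cell markers.

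The number of genes detected with at least 10 counts, after thinning each library to the smallest total, was 12707 ± 598 in blood and 13510 ± 596 in synovial fluid. The difference of 802 genes had a two-sided exact permutation p of 0.0498 over 462 assignments, 0.249 after adjustment over 5 library measures, and 0.055 when assignments were kept within the inferred pools. In 8 of the 11 tests that left out a library the exact permutation p was 0.05 or more. The shares of MALAT1 and of signal recognition particle RNA differed by -0.88 and -0.74 percentage points, with exact permutation p of 0.695 and 0.158. The share of the 100 most abundant genes had p = 0.916 and the total count p = 0.110 by the same exact test.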

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

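Tests of why blood library 1 differs were chosen after its values were seen. Outliers are libraries whose gap to the nearest library of their group passes Dixon's critical value, in log2 CPM for genes and list means. Of 76 groups of library measures and list means 13 gave an outlier, and of 142 groups of single genes 26 did, where chance alone gives about 1 in 20 (3.8 and 7.1). Of these 39 results 18 were in blood library 1 and 18 in synovial fluid library 5.

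Synovial fluid library 5 had 11.8% of its counts on MALAT1, a nuclear noncoding RNA, where the next synovial fluid library had 4.61%. Its 100 most abundant genes held 39.99% of counts against 31.5%, and its TMM factor was 0.628 against 1.03. The mean over the maturation list was 9.83 against 5.58 log2 CPM, over glycolysis 8.13 against 6.53, over hypoxia response 6.40 against 3.82, and over cell cycle 1.79 against 2.98. It was the highest synovial fluid library for IL21R at 8.22, TBC1D4 at 10.58, RFX5 at 7.91, CD86 at 9.27 and IL6 at 2.45. It was the lowest for SNX22 at 5.33, CADM1 at 5.93, THBD at 6.09, IRAK1 at 5.53, CD200R1 at -1.49 and COL6A1 at 1.19. CCR7 reached 3467 CPM there, TRAF1 4279 CPM and BIRC3 9023 CPM.

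Blood library 1 had a median correlation of 0.650 with its own group. Its list means were 6.49 for MHC class II, 8.77 for glycolysis, 7.21 for hypoxia response, 3.73 for oxidative phosphorylation and 6.93 for ribosomal proteins. CCND1, GNAO1, XCR1, CLEC9A, BATF3 and APOE were at 0 counts, which is -2.96 on this scale, and CADM1 was at -2.27. CD83 was lowest at 7.62, MCM5 at 3.67 and RPL37 at 6.53, while HK2 was highest at 11.06 and DNAJC3 at 9.26. Blood library 4 was lowest for MS4A1 at -2.96 and highest for COL6A1 at 1.67, and blood library 5 was highest for CD200R1 at -0.66, a level of a few counts.

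The near absence of type 1 dendritic cell transcripts from blood library 1 was weighed further. Too few reads cannot account for it, since at the level of the other 4 blood libraries it would hold 964 counts of CLEC9A and it held 0. Unstimulated blood monocytes in place of dendritic cells cannot be judged from their markers, which disagree. LYZ, S100A8 and S100A9, abundant in such cells, averaged -1.03 log2 units relative to the other 4 blood libraries. S100A8 (37.7 CPM) lay inside the range of those libraries (24.7 to 44.9 CPM). VCAN (9667 CPM), THBS1 (27761 CPM) and CD14 (343 CPM) were the highest of the group. The mean of the monocyte list was 6.62 log2 CPM, against 4.31 to 6.49 in the other blood libraries. Another CD141-bearing cell, or cells in an activated state with interferon-stimulated genes such as RSAD2 (1632 CPM) and with SPP1 (3879 CPM), stays open and was not tested. Other cells were weighed here as a technical source. The labels give no biological factor within the blood group, so none was tested.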

How the results depend on the processing

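Calls of genes depended strongly on which libraries were used and on the test, while 0 genes called in the original fit were called the opposite way under any of these settings. Without a filter on low counts edgeR called 239 lower genes and 11 lists. DESeq2 called 1242 higher and 992 lower genes, and limma voom with quality weights 2579 and 2011. With the inferred pool as a term 232 genes were lower. Within inferred pool A 0 genes were higher and 0 lower by edgeR, with 1131 at an unadjusted p under 0.05, and within pool B 190 and 193. Blood library 1 was 1 of the 2 blood libraries in pool A. Leaving out each library in turn gave 133 to 1380 higher genes (lowest without blood library 4 or 5, highest without blood library 1) and 96 to 1180 lower genes (lowest without blood library 5, highest without blood library 1). Settings chosen after seeing the data gave 1858 and 1599 without blood library 1 and synovial fluid library 5, and 1021 and 948 without blood library 1 and synovial fluid libraries 2 and 4. With the correlation estimated 0 lists were called, against 5 by fry. The difference in detected genes, 802, had an exact permutation p of 0.055 within pools and ran from 664 to 1011 as each library was left out, with 8 of 11 exact p at 0.05 or more. It was 2305 with at least 1 count (exact p 0.00866) and 1358 without thinning (exact p 0.0216). Apart from the filters, the test and the number of libraries, the cause was not tested.

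The label numbers do not pair the subjects, and the correlations of same-numbered libraries were -0.18, -0.03, -0.04, -0.06 and 0.12. With the number as a block edgeR called 0 higher and 0 lower genes, with 1999 at an unadjusted p under 0.05, and the block fit used only the shared numbers and so fewer libraries. Its list count was 8. Only number 6 correlated best with its own number. Among named genes 1370 of 1687 values under other settings stayed on the same side of the threshold, 265 lost the call, 51 gained it and 1 was newly called against its original sign: TNF was lower by voom with quality weights (-2.22, adjusted p = 0.0147, over a range of 0.0147 to 1). Of 612 list values 556 stayed on the same side, 23 lost the call and 33 gained it. Among those on the same side the sign turned in 20 gene values and in 50 list medians. Of 43 called named genes 19 kept the call with any single library left out that allowed a test, and 21 lost it in 2 or more such fits. The mitochondrial share was not run.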

Other observations

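Tests of XCR1, of the role of blood library 1 and of FN1 were chosen after their values were seen. The genes of this paragraph were also chosen after their values were seen, from those with the smallest edgeR p. REEP3, an endoplasmic reticulum shaping protein, rose from 16.2 ± 4.20 CPM in blood to 179 ± 53.0 CPM in synovial fluid (log2 fold change 3.47 ± 0.30, edgeR adjusted p = 0.000622). GAS6, a ligand of the TAM receptor kinases, rose by 3.87 ± 0.46, CD226, an adhesion receptor of lymphocytes, by 3.82 ± 0.46, and BTLA, an inhibitory receptor, by 3.90 ± 0.55 on the log2 scale. ROBO1, a guidance receptor, rose from 14.0 ± 7.82 to 312 ± 181 CPM. PRKAR1A, a regulatory subunit of protein kinase A, rose by 2.33 ± 0.32. C15orf39 went from 630 ± 208 to 111 ± 21.1 CPM (-2.50 ± 0.28, adjusted p = 0.00351), and TLE4, a transcriptional corepressor, had a log2 fold change of -1.97 ± 0.27. Each of these genes separated the groups without overlap.

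Whether chance could give the calls was examined with 100 splits of the 11 libraries, drawn from 462. The real split was the only 1 of the 100 with 424 or more higher genes, where the highest other split gave 153. It was also the only 1 with 374 or more lower genes, where the highest other gave 298. The same split, with 1 synovial fluid library exchanged for a blood library, gave both 153 and 298. Chance is thus unlikely for both counts but not excluded, since most of the possible splits were not drawn. For gene lists 74 of the 100 splits called 7 or more lists and the highest other called 16, so chance is not excluded for the list counts. Camera with a preset correlation thus answers to differences between single libraries in these data.

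Of 19 type 1 dendritic cell genes 4 were called higher in synovial fluid, while CLEC9A, CADM1 and BATF3 were not called and TLR3, DNASE1L3 and ID2 had log2 fold changes of -1.52, -0.15 and -0.19 (not called). Without blood library 1 TLR3, DNASE1L3 and ID2 had -1.89 (edgeR adjusted p = 0.0508), -0.52 and -0.53, still not called. CADM1 had 1.90 in that fit and was called. TLR3, DNASE1L3 and ID2 were not part of the ratio tests below. The list as a whole had an adjusted p of 0.821 with an estimated correlation. A candidate explanation for the 4 calls is a smaller share of these cells in the blood libraries. Blood library 1 alone does not account for it, since 10 list members were called without that library. A share of cells would move XCR1 by the same factor as CLEC9A, CADM1, BATF3 and CLNK if all came from these cells alone. That condition was not tested. XCR1 rose by 2.82 log2 units more than their mean (two-sided exact permutation p = 0.00476 over 210 assignments, 4 blood against 6 synovial fluid libraries). Under that condition the difference argues against a share as the whole cause for XCR1. XCR1 was chosen for this test after its values were seen, and the p is not adjusted for that choice. For CLEC9A, CADM1, BATF3 and CLNK the largest difference of log2 folds was 1.06, CLNK against CLEC9A (exact permutation p = 0.0143, adjusted over 6 pairs 0.0786), so a changed share and a change within the cells cannot be told apart with 10 libraries. The tissue and the disease stay open and were not tested apart.

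FN1 in synovial fluid cells may come from other cells of the joint or from the sorted cells themselves. Synovial fibroblasts are argued against as the main source of FN1, because COL1A1, COL1A2 and COL3A1, abundant in them, together reached at most 1.84% of FN1 in any of the 6 synovial fluid libraries. A small share of fibroblasts is not excluded, since COL6A1 was called higher (26.0 CPM in synovial fluid) and COL1A2 averaged 4.17 CPM there against 0.381 CPM in blood. Macrophages, which a CD141 bead sort can retain, stay open. Over the 6 synovial fluid libraries FN1 rose with the mean of 8 macrophage markers with Pearson r = 0.770 (exact permutation p = 0.0653) and Spearman rho = 0.657 (p = 0.175). Without the 2 libraries whose marker mean lay farthest from the median r was -0.11. Leaving these out also removes much of the range of the markers, so that r cannot decide the question. Macrophages and a change in the sorted cells cannot be told apart.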
